A study of Drosophila melanogaster with 12 samples.

How the data were processed

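Total RNA from 12 samples of male Drosophila melanogaster, labelled as 1 day old, was hybridised to 1-colour (Cy3) Agilent expression arrays. The flies had been exposed to 0.0312 µM or 0.312 µM methyl parathion, an organophosphate insecticide, or to the solvent DMSO below 0.03%, for 24 h or 48 h. Per the labels' protocols, food was kept at 23 to 25 °C and 500 ng of RNA entered each labelling reaction. The labels do not say whether whole flies or a tissue were extracted. They do not say how many flies made a sample or whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

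Per the file headers, spot intensity was extracted by the authors with Agilent Feature Extraction 11.5.1.1, with spatial and multiplicative detrending, background subtraction and surrogate values for dim spots, and with no scaling between arrays. The raw mean spot intensity and the median local background intensity, as deposited, were used for 1 alternative. Other columns hold flags of 0 or 1 for spots well above background, saturated spots and outlier spots. The authors' deposited value table is on a log2 scale. Against the log2 scanner signal minus its 75th percentile, its columns correlated across probes at 0.998 to 0.999, and their medians lay between -2.85 and -2.65, so its scale and centring match that scaling.

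The main values were log2 of the processed intensity minus the 75th percentile of each array. Of the spots, 61657 were not controls and were used, and 1319 control spots were left out. Between 629 and 1327 spots per array carried an outlier flag and were dropped, and 0 spots were saturated. Spots of the same probe were averaged, which left 34630 probes, of which 1251 were printed more than once. Between 69.5% and 77.0% of probes were well above background on an array, and the 75th percentile of the signal ranged from 1092 to 2116. The number of arrays, 2 per group, limits the precision.

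Probe names came from the files and were matched through their accessions and names to NCBI's RefSeq gene table (assembly Release 6), used only for names. Of the probes, 22770 matched 1 gene, 148 had a name and an accession of different genes and were kept under the file's name, and 11712 did not match and kept the file's name. The matched probes covered 13506 genes, of which 5794 had more than 1 probe. Such a gene was represented by its probe of highest mean signal, and probes that differ are given beside the gene. The sequence of 418 probes was listed under more than 1 gene. The chromosome in the files was that of the matched gene for 23.6% of 21643 probes compared (19.1% and 97.6% in the 2 probe families of the array), so no coordinates are printed. Probe sequences were not aligned to check the names.

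Features were kept when their probe was well above background on both arrays of at least 1 group, which left 18008 features (12395 NCBI genes and 5613 other names). The 11 comparisons were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), in 1 model with a mean for each of the 6 groups and 6 residual degrees of freedom. The prior added 2.44 degrees of freedom, and the median SD within groups was 0.263 on the log2 scale. Adjusted p-values are Benjamini-Hochberg values over all features of a comparison, with a threshold of 0.05. Effects over both times are the mean of the 24 h and 48 h effects. A time difference is the effect at 48 h minus the effect at 24 h. Gene values are log2 fold changes ± SE from this fit.

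Where a gene was not well above background on either array of a group, its fold is given as a bound. The bound set the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the gene's own value and the lowest signal among probes well above background. No bound is given where it fell under 1 or where both groups were dim. For effects over both times and time differences, no size is given for a gene not well above background on either array of at least 1 of the 4 groups, and its test rests on such values.

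The 30 gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within each comparison. They were cholinergic synapse, cytochrome P450, glutathione S-transferases, UDP-glucuronosyltransferases, carboxylesterases, antioxidant and metallothionein, heat shock proteins and chaperones, antimicrobial peptides and Bomanins, Toll and Imd pathway, Turandot and Jak/Stat, apoptosis and JNK, oxidative phosphorylation, ribosomal proteins, proteasome, insulin, Akh and starvation, lipid synthesis and desaturation, digestive enzymes, male accessory gland, testis, yolk and eggshell, muscle, photoreceptor, neuron, fat body, hemocyte and melanization, cuticle proteins, odorant-binding proteins, circadian clock, ecdysone and juvenile hormone, and activity-regulated genes. The fat body list shares the 3 yolk protein genes with the yolk and eggshell list, the clock list shares to with the fat body list, and Est-6, Hr38, Jra, kay, puc and Obp44a are also each in 2 lists. The accessory gland list holds Acp1, an adult cuticle protein gene, by its symbol stem, and without it, a test added after the data were seen, the same 7 comparisons were called. Camera with the correlation estimated for each list and limma's fry were run beside it. With the estimated correlation and with fry, 0 of the 180 tests of a dose against controls passed at an adjusted p of 0.05, and 6 had an unadjusted p under 0.05 with the estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone.

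The groups, comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. Named genes were, for a dose against controls, the 10 largest increases and 10 largest decreases among genes past the threshold whose treated arrays all lay on 1 side of their controls, with a symbol other than a CG or CR number, plus the 3 largest each way with such a number. The other comparisons took 5 each way, with no condition on the side. Where no gene passed, the 5 genes each way with the smallest unadjusted p and such a symbol were named, as values that did not pass. Those of them with no size to give were mostly left out. This fallback was also used where the only genes that passed had a CG number or no NCBI match, an extension chosen after the counts were seen. A gene with a lethal-locus symbol is given by its locus tag, CG8799. CO286976, the array's name for a probe without an NCBI match, lies outside the rule and was named, after its values were seen, because 5 or fewer features passed. Up to 4 members of a list with the smallest p were open to naming, and Ace, Cyp6g1, Cyp6a2, Cyp12d1-p, GstD1, GstD2, Hsp70Bc and DptB were always named against controls.

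Alternatives were normexp background correction with an offset of 50, quantile scaling, centring on the median of probes well above background on all 12 arrays, no filter on dim probes, only probes well above background on all arrays, the mean of a gene's probes, the authors' deposited values, a trended robust prior, a fit to the 6 arrays of 1 time, slide as an additive block, a replicate block, other thresholds, and leaving out each array. With an array left out, its group holds 1 array, which is assumed to vary like the other groups. A fit to NCBI genes only was added after the data were seen. Each time had its own slide, so comparisons within a time lie within a slide, but time and slide cannot be told apart.

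The steps were tested on simulated data with known changes over 17989 genes. For the high dose against controls at 24 h, 26.9% of 2-fold, 80.6% of 4-fold and 90.9% of 8-fold changes were recovered, with 5 false calls. Over both times the shares were 50.7%, 92.5% and 97.0%, with 12 false calls. A list of 24 genes shifted by -0.50 was called at -0.54 with 0 others, but other splits of real arrays called up to 15. Values were handled in data.table (1.17.8), Python 3.11.15 and pandas 2.3.3 and drawn with matplotlib 3.10.9.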

Results

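Gene expression was measured on 12 arrays of male flies in 6 groups of 2 samples: solvent controls, a low dose (0.0312 µM) and a high dose (0.312 µM) of methyl parathion, each at 24 h and at 48 h. Methyl parathion is an organophosphate insecticide whose oxygen analogue inhibits acetylcholinesterase, and the series asked how organisms differ in their sensitivity to such agents. Probes well above background numbered 24053 to 26682 of 34630 per array, highest on the 48 h control arrays (74.3% and 77.0% on replicates 1 and 2). Pairs of arrays of the same group correlated across probes at 0.976 to 0.986 with a median of 0.984, and pairs of other groups at the same time at 0.968 to 0.989 with a median of 0.982. The first 3 principal components took 26.6%, 19.6% and 11% of the variance. On both slides only controls lay in row 1 and only low-dose samples in columns 1 and 2. Position and dose cannot be told apart.

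Gene values below are log2 fold changes ± SE from limma, with 2 arrays in each group. Values of a gene list are the median log2 fold change of its measured members and, as its test, camera's adjusted p at a preset correlation. Lists were called 40 times among 180 tests of a dose against controls. With the correlation estimated from these arrays, or fry, 0 were called, so each list has its adjusted p under that estimate. Over both times, regrouped arrays often matched the call count. Among called lists median, mean and test had the same sign. Arrays are named by group and replicate, such as control 1, and where leaving 1 out ended a call or moved a called value by over 1.5 times, the value without it is given.

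**Figure D1:**
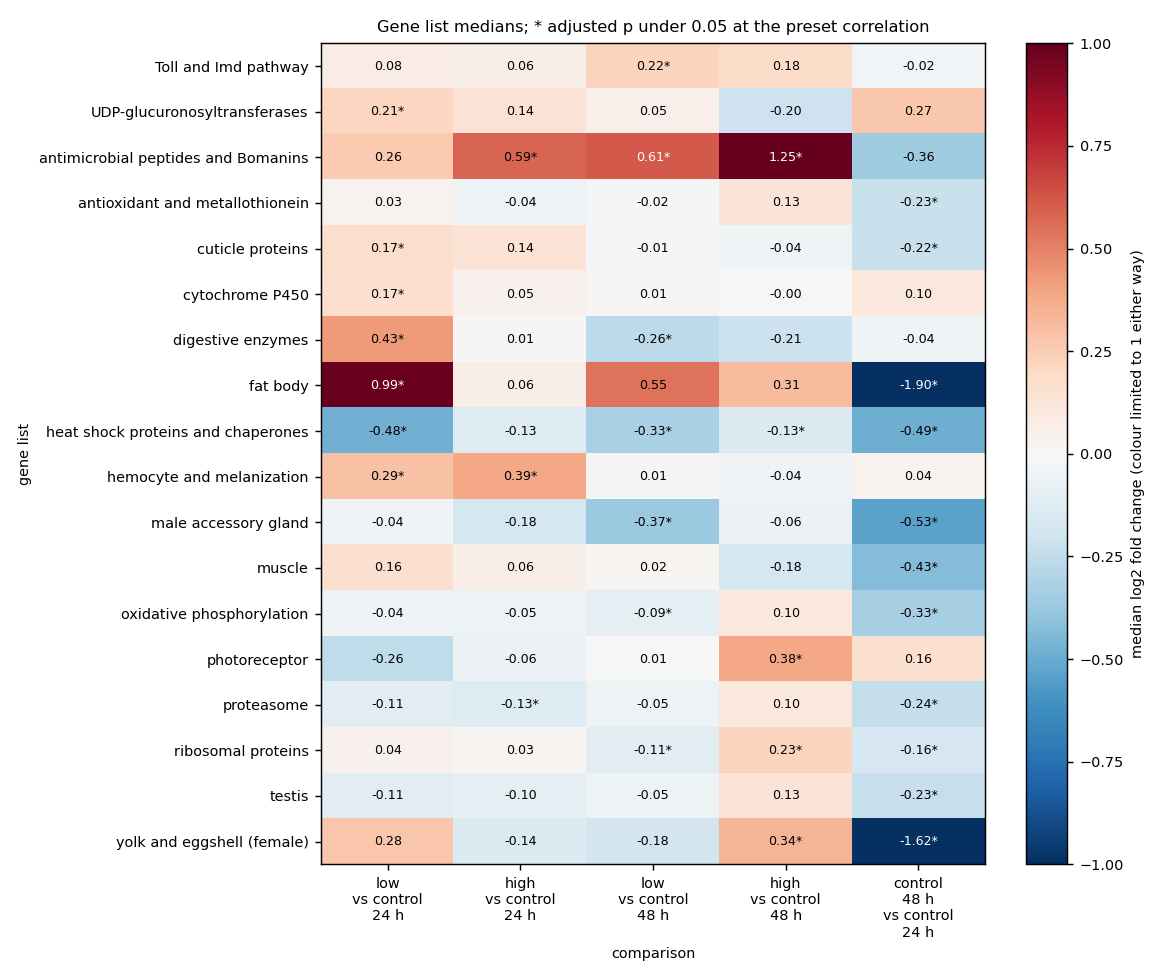
Median log2 fold change of the members of the gene lists called in any of the comparisons shown (vertical axis), for the 4 comparisons of a dose with its controls and that of 48 h with 24 h controls (horizontal axis), with an asterisk where camera's adjusted p at the preset correlation was under 0.05. Heat shock proteins lay at -0.48 and -0.33 at the low dose, and the yolk and eggshell list at -1.62 in the control comparison.

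Low-dose flies at 24 h had higher transcripts of digestive enzymes, the secreted proteases, maltases, amylases and lysozymes of the gut, with 43 of 52 members above 0 and a median of 0.43. The trypsin gene thetaTry was at 1.84 ± 0.62, the maltase Mal-A7 at 2.21 ± 0.78 and Amyrel, a relative of amylase, at 2.04 ± 0.82. Heat shock proteins and chaperones, which refold proteins under stress, were lower, with 21 of 24 members below 0 and a median of -0.48. Their smallest p were for the small heat shock genes Hsp26, at -1.20 ± 0.32, and Hsp27, at -1.04 ± 0.35, and the inducible Hsp70Bb, at -1.20 ± 0.45, and Hsp70Bc, at -1.32 ± 0.51. Hemocyte and melanization genes were higher in 17 of 20 members with a median of 0.29, among them the phagocytic receptor genes NimC2, at 1.14 ± 0.33, and eater, at 1.19 ± 0.48.

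The adjusted p was 5.98e-07 for digestive enzymes (0.614 with the estimate), 2.17e-06 for heat shock proteins (0.566 with the estimate) and 0.000791 for hemocyte genes (0.566 with the estimate), and leaving out any array ended none of the 3 calls. With limma, 0 members of these 3 lists passed over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 4 digestive enzymes, 8 heat shock genes and 3 hemocyte genes. Fat body genes, which encode storage and lipid transport proteins, had a median of 0.99 with 13 of 15 members higher (adjusted p = 0.000401, 0.566 with the estimate). That median was 0.56 without control 1 and 0.57 without low 1. UDP-glucuronosyltransferases (UGTs), which conjugate foreign compounds and hormones, had a median of 0.21 with 22 of 29 higher (adjusted p = 0.0013, 0.566 with the estimate), and 0.35 without low 1. Ugt35E1, not well above background in controls, was at least 2.57-fold higher. Cytochrome P450 genes, whose enzymes oxidise many insecticides, had a median of 0.17 with 52 of 80 higher (adjusted p = 0.0178, 0.614 with the estimate), including Cyp6a13 at 0.91 ± 0.21. Their call ended without control 2 (0.09) and without low 2 (0.10), with normexp (adjusted p = 0.0794) and without the dim filter (adjusted p = 0.0826). Cuticle proteins had a median of 0.17 with 50 of 74 higher (adjusted p = 0.0202, 0.851 with the estimate). It was -0.02 without control 1, 0.37 without control 2 and 0.11 without low 1, and the call ended in the first and the last of these and without the dim filter (adjusted p = 0.239). Of these 4 lists, 0 members passed over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 there were 0 fat body genes, 2 UGTs, 7 P450 genes (5 higher and 2 lower) and 2 cuticle genes.

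Among single genes, limma called 0 of 18008 in low-dose flies at 24 h (smallest adjusted p = 0.0725), with 950 at an unadjusted p under 0.05 where chance gives 900. The count was 5 without control 2, 3 without low 1, 14 without low 2 and 1 without either low array of 48 h. CtsL2, a cathepsin L-like protease gene, had the smallest adjusted p and was at least 9.46-fold higher, since it was not well above background in controls. Others not passing were Dci, an enzyme of fatty acid oxidation, at 2.26 ± 0.32, Hacl, which splits hydroxyacyl-CoA, at 0.84 ± 0.17, and asRNA:Eig63F-2 at 1.97 ± 0.41. Lower were the kinase gene Lrrk at -1.0 ± 0.19, the annexin AnxB11 at -0.64 ± 0.14, the growth regulator Myc at -0.97 ± 0.23 and Srp68, of the signal recognition particle, at -3.44 ± 0.89. The 3 probes of AnxB11 ranged from -0.64 to -0.32.

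**Figure D2:**
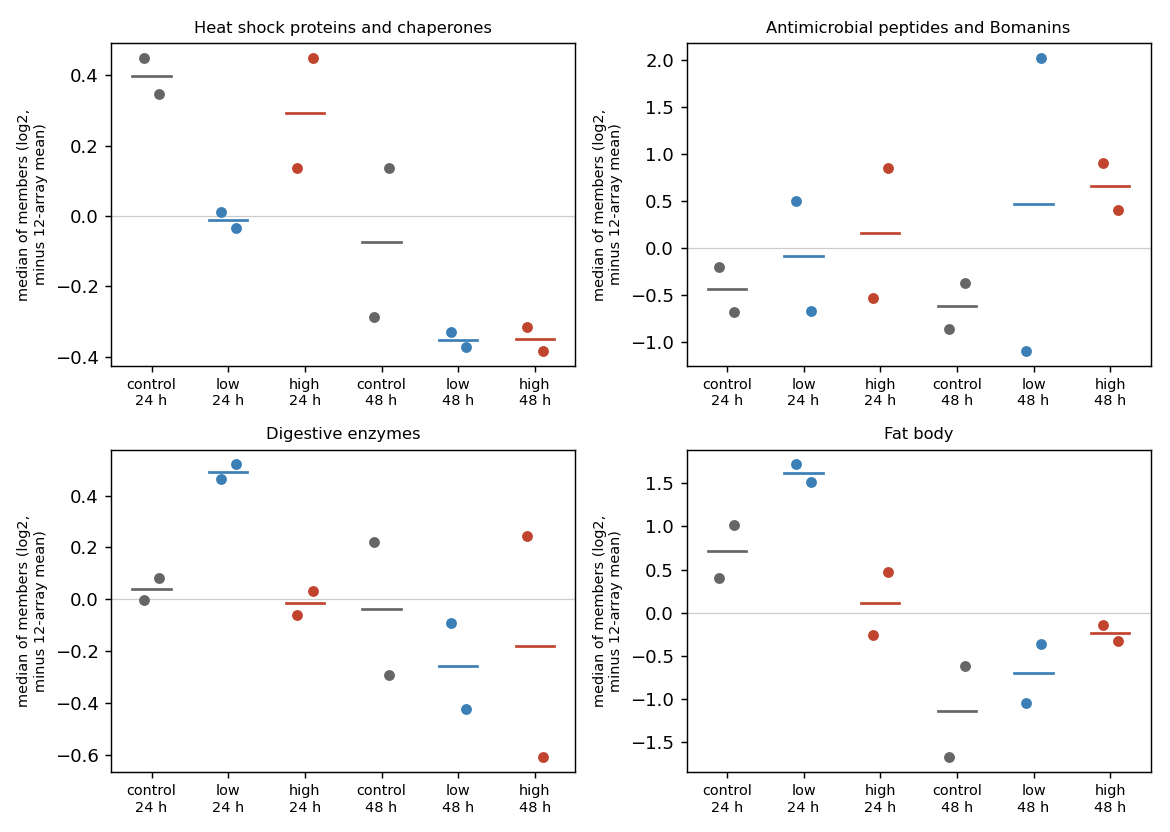
Median of a list's members on each array (points, log2, each gene minus its mean over 12 arrays, with the group mean as a line) for the 6 groups on the horizontal axis. The heat shock list lay at 0.45 and 0.35 on the 24 h control arrays and at 0.01 and -0.03 on the low-dose arrays of that time, while antimicrobial peptides spanned -1.10 to 2.02 between the 2 low-dose arrays of 48 h.

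High-dose flies at 24 h had higher hemocyte and melanization genes, with 17 of 20 members above 0 and a median of 0.39. The collagen gene vkg was at 0.66 ± 0.21, the scavenger receptor Sr-CI at 0.92 ± 0.33, NimC2 at 0.83 ± 0.33 and eater at 1.16 ± 0.48. Antimicrobial peptides and Bomanins, the secreted effectors of the humoral immune response, were higher in 24 of 25 members with a median of 0.59, led by the drosomycin-like genes Drsl3, at 1.38 ± 0.31, and Drsl4, at 0.57 ± 0.18. Proteasome genes were slightly lower, with 37 of 45 members below 0, a median of -0.13 and Prosalpha2 at -0.43 ± 0.19. The CO286976 probe, named for an expressed sequence tag without an NCBI match, was the only feature that passed limma over all features and was at least 5.49-fold higher (adjusted p = 0.000337), being well above background on the high-dose arrays of 24 h alone.

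The adjusted p was 0.000111 for hemocyte genes, 0.00807 for antimicrobial peptides and 0.0134 for the proteasome at the preset correlation, and each had an adjusted p = 0.953 with an estimated correlation. With limma, 0 members passed over all genes. Adjusted over the list alone, 1 antimicrobial peptide gene (Drsl3) passed, with 2 higher at an unadjusted p under 0.05, while 0 hemocyte and 0 proteasome genes passed, with 4 and 0 at that unadjusted p. The hemocyte call ended without high 2 (0.26), the antimicrobial call ended without control 2 (0.30) and without high 2 (-0.19) and its median was 1.38 without high 1, and the proteasome call ended without control 2 (-0.03) and high 2 (-0.08), with -0.23 without control 1. The proteasome call also ended under quantile scaling (-0.11, adjusted p = 0.0882). An unadjusted p under 0.05 held for 726 features, and the count of 1 became 4 and 6 without control 1 and control 2, 5 and 2 without high 1 and high 2, and 3 without either low array of 48 h.

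High-dose values at 24 h that did not pass included VGAT, the vesicular GABA transporter, at least 3.32-fold higher, Dci at 1.63 ± 0.32, asRNA:Eig63F-2 at 2.04 ± 0.41 and Osi17, higher without a size. Lower were FarO, a fatty acyl-CoA reductase, at -0.96 ± 0.20, the transcription factor sr at -1.73 ± 0.37, hfw at -1.0 ± 0.23, the splicing factor crn at -0.97 ± 0.23 and the odorant-binding protein Obp56b, at least 2.10-fold lower.

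Between the doses at 24 h, high-dose flies had lower digestive enzymes than low-dose flies, with 44 of 52 members below 0 and a median of -0.44. The trypsin lambdaTry was at -1.34 ± 0.30, the maltase Mal-A3 at -1.62 ± 0.45 and the Jonah proteases Jon25Biii and Jon25Bii at -0.68 ± 0.20 and -1.53 ± 0.48. Heat shock proteins were higher in 19 of 24 members with a median of 0.34, with Hsp67Bc at 1.17 ± 0.34, Hsp26 at 1.08 ± 0.32 and Hsp27 at 1.15 ± 0.35. CtsL2 was at least 9.51-fold lower at the high dose (adjusted p = 0.0076), since it was well above background on the 2 low-dose arrays alone, and CO286976 was at least 4.84-fold higher (adjusted p = 0.000304).

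The digestive enzyme difference had an adjusted p of 5.91e-12 (0.658 with the estimate) and kept its call without any array. The heat shock difference had an adjusted p of 4.41e-06 (0.602 with the estimate), and its median was 0.61 without high 1 and 0.12, no longer called, without high 2. Fat body genes had a median of -0.56 with 14 of 15 lower (adjusted p = 0.000191, 0.602 with the estimate), led by the storage protein Lsp1gamma at -1.37 ± 0.75, and were at -0.37 without low 1 and at -0.07, not called, without high 1. Yolk and eggshell genes, active in females, had a median of -0.47 with 12 of 17 lower (adjusted p = 0.00266, 0.658 with the estimate), with the eggshell gene Cp36 at -1.80 ± 0.66. Their median was -1.34 without high 1, and the call ended without low 1 (-0.37) and without high 2 (0.05). The other called lists were small shifts: UGTs at -0.18 with 24 of 29 lower (adjusted p = 0.0091, 0.658 with the estimate), photoreceptor genes at 0.19 with 20 of 25 higher (adjusted p = 0.0091, 0.921 with the estimate) and P450 genes at -0.15 with 57 of 80 lower (adjusted p = 0.014, 0.661 with the estimate). All 3 lost the call without low 2 (-0.13, 0.12 and -0.06) and without high 1 (-0.18, 0.16 and -0.13). The P450 list held Cyp4d1 at -1.98 ± 0.38 and Cyp308a1 at 0.89 ± 0.25. Male accessory gland genes, whose products enter the seminal fluid, were at -0.15 with 41 of 50 lower (adjusted p = 0.0151, 0.921 with the estimate). The median was -0.38 without high 1, and the call ended without low 1 (-0.10) or high 2 (0.11). Antimicrobial peptides were at 0.27 with 16 of 25 higher (adjusted p = 0.0352, 0.921 with the estimate). They were at 0.77 without low 1 and 1.12 without high 1, and the call ended without low 2 (-0.04), high 2 (-0.34) or either high array of 48 h (0.27). That list also lost its call on the authors' deposited values (adjusted p = 0.0758) and under quantile scaling (adjusted p = 0.0573). P450 and accessory gland genes lost theirs with normexp (adjusted p = 0.0656 and 0.0827) and without the dim filter (0.145 and 0.105), and UGTs without that filter (0.068).

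In these 9 lists limma called 0 members over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 9 digestive enzymes, 4 heat shock genes, 1 yolk and eggshell gene, 1 photoreceptor gene, 2 P450 genes, 2 antimicrobial peptide genes and 0 genes of the other 3 lists. Among all features 414 reached that unadjusted p between the doses at 24 h. The count of 2 became 5 without low 1, 15 without low 2, 4 without high 1 and 5 without high 2.

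Low-dose flies at 48 h had lower male accessory gland genes, with 46 of 50 members below 0 and a median of -0.37, including the seminal fluid genes Acp26Aa, at -0.75 ± 0.35, and Sfp79B, at -1.10 ± 0.52. Heat shock proteins were again lower than controls, in 22 of 24 members with a median of -0.33, with Hsp70Aa at -0.94 ± 0.34, Hsp70Bbb at -1.23 ± 0.48 and Hsp68 at -0.77 ± 0.33. Digestive enzymes were lower in 46 of 52 members with a median of -0.26, including Npc2e, a sterol-binding protein, at -1.87 ± 0.66 and the lysozymes LysC and LysX at -1.46 ± 0.66 and -1.57 ± 0.82. CG7606, known by its CG number, was the only gene that passed limma over all features, and it was at least 1.5-fold lower (adjusted p = 0.0132), being well above background on the 48 h control arrays alone.

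All lists called at the low dose and 48 h had an adjusted p = 0.957 with an estimated correlation. The accessory gland list had an adjusted p of 1.59e-08. The median was -0.21 without control 1 and -0.14, not called, without low 2. The heat shock list had an adjusted p of 5.85e-06. The median was -0.16 without low 2 and -0.19, not called, without control 2. The digestive enzyme list had an adjusted p of 0.00016. The median was -0.46 without control 2, and the call ended without control 1 (-0.05, where the test turned upward) and without low 2 (-0.07). Antimicrobial peptides were higher in 21 of 25 members with a median of 0.61 (adjusted p = 0.00273), and genes of the Toll and Imd pathways, which switch on these peptides, in 24 of 31 with a median of 0.22 (adjusted p = 0.000741). Both rested on low 2: without it the antimicrobial list was lower at -0.55 (adjusted p = 0.036) and the pathway list was at -0.15 and not called, while without low 1 they were at 2.35 and 0.65. The diptericin gene DptB was at 3.73 ± 2.17, while Drsl4 was at -0.69 ± 0.18, and the recognition protein GNBP1 was at 0.65 ± 0.21.

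Ribosomal proteins at the low dose and 48 h were at -0.11 with 85 of 93 lower (adjusted p = 0.000113, and this list and the next had an adjusted p = 0.957 with an estimated correlation), with RpL23 at -0.30 ± 0.15. They were at -0.20 without low 2, and the call ended without control 1 (-0.05) or low 1 (-0.03). Oxidative phosphorylation (OXPHOS) genes were at -0.09 with 80 of 91 lower (adjusted p = 0.004), with ND-B14 at -0.40 ± 0.22, were at -0.14 without control 1, and were not called without control 2 (-0.09) or low 2 (-0.12). Under quantile scaling both lists were at -0.06 and still called, and the antimicrobial median was 0.94 with dim values raised to the lowest signal well above background. In these 7 lists limma called 0 members over all genes or adjusted over the list alone. The unadjusted p was under 0.05 for 3 heat shock genes, 1 digestive enzyme, 1 Toll and Imd gene, 2 antimicrobial peptide genes (both lower) and 0 genes of the other 3.

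Low-dose values at 48 h that did not pass were the feeding and clock gene to at 1.44 ± 0.34, Fad2, a fatty acid desaturase, at least 3.86-fold higher, the clock neuropeptide gene Pdf at 0.99 ± 0.28, Nha2 at 0.71 ± 0.20 and Irbp at 0.86 ± 0.26. Lower were Nepl7 at -1.78 ± 0.34, though its other probe was at 0.44, Miox, which degrades inositol, at -1.55 ± 0.31, the cuticle gene Lcp3, at least 4.68-fold lower, OtopLc at -1.19 ± 0.26 and Ance-4 at -1.16 ± 0.26. At an unadjusted p under 0.05 there were 408 features, fewer than the 900 that chance gives. The count of 1 became 18 without control 2, 39 without low 1, 3 without low 2 and 0 without control 1. It was also 0 without either control array of 24 h or either high array of 48 h, 3 without either low array of 24 h and 2 without either high array of 24 h.

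High-dose flies at 48 h had higher antimicrobial peptides and Bomanins, with 24 of 25 members above 0 and a median of 1.248. The drosomycin-like genes Drsl5, at 1.18 ± 0.31, Drsl4, at 0.55 ± 0.18 and Drsl6, at 0.91 ± 0.42, had the smallest p. Ribosomal proteins were higher in 87 of 93 members with a median of 0.23, including RpS20, at 0.55 ± 0.18, and RpS29, at 0.56 ± 0.19, while RpL34b was at -0.68 ± 0.17. Photoreceptor genes were higher in 22 of 25 with a median of 0.38, including the arrestin Arr1, at 0.78 ± 0.23, the kinase inaC, at 0.83 ± 0.27, and the opsin Rh4, at 0.78 ± 0.26. Heat shock proteins were lower in 17 of 24 with a median of -0.13, and the inducible Hsp70Bbb and Hsp70Aa and the chaperone Hsp83 fell, at -2.55 ± 0.48, -1.41 ± 0.34 and -0.69 ± 0.19, when adjusted over the list alone.

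All lists called at the high dose and 48 h had an adjusted p = 0.628 with an estimated correlation. At the preset value the adjusted p was 3.49e-05 for antimicrobial peptides, which kept the call and a median within 1.5 times without any array, and 1.30e-09 for ribosomal proteins, whose median was 0.14 without high 1 and 0.34 without high 2. It was 0.000119 for photoreceptor genes, at 0.65 without high 1 and 0.22, not called, without high 2. It was 0.00828 for heat shock proteins, at -0.25 without control 1 and -0.31 without high 1, and the call ended without control 2 (-0.19) or high 2 (-0.33). Yolk and eggshell genes were at 0.34 with 15 of 17 higher (adjusted p = 0.0268), and Yp1, a yolk protein not well above background in controls, was at least 2.57-fold higher. That call ended without control 1 (0.46), either low array (0.34), high 1 (0.54) or high 2 (0.33), and the median was 0.57 without control 2. It also ended with normexp (adjusted p = 0.0868) and without the dim filter (0.0647). Quantile scaling moved the yolk and eggshell median to 0.53 and the ribosomal median to 0.13, both still called. With limma, 0 members of the 5 lists passed over all genes. Adjusted over the list alone, 3 heat shock genes fell and 0 of the other lists passed, with 7 heat shock, 2 antimicrobial, 15 ribosomal (14 higher and 1 lower), 4 photoreceptor and 1 yolk and eggshell gene at an unadjusted p under 0.05.

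CG7606 was again the only feature called over all genes at the high dose and 48 h, at least 1.33-fold lower (adjusted p = 0.0179). Values that did not pass were the taste receptor Gr58c, at least 3.19-fold higher, the ion channel subunit ppk21, at least 2.46-fold higher, the clock gene tim at 0.98 ± 0.20, Pdf at 1.29 ± 0.28 and GstE14, a glutathione transferase, at 0.99 ± 0.22. The other probe of tim was at 0.05. Lower were CG8799 at -2.78 ± 0.39, sphe at -2.84 ± 0.42, VGAT, at least 1.60-fold lower, the cuticle gene Cpr76Bd at -1.96 ± 0.34 and the transporter Mrp5 at -1.50 ± 0.26. An unadjusted p under 0.05 was reached by 1921 features, 743 higher and 1178 lower, above the 900 that chance gives. The count of 1 became 3 without control 1, 27 without control 2, 8 without high 1, 10 without high 2, 3 without either low array of 48 h and 0 without any array of 24 h.

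**Figure D3:**
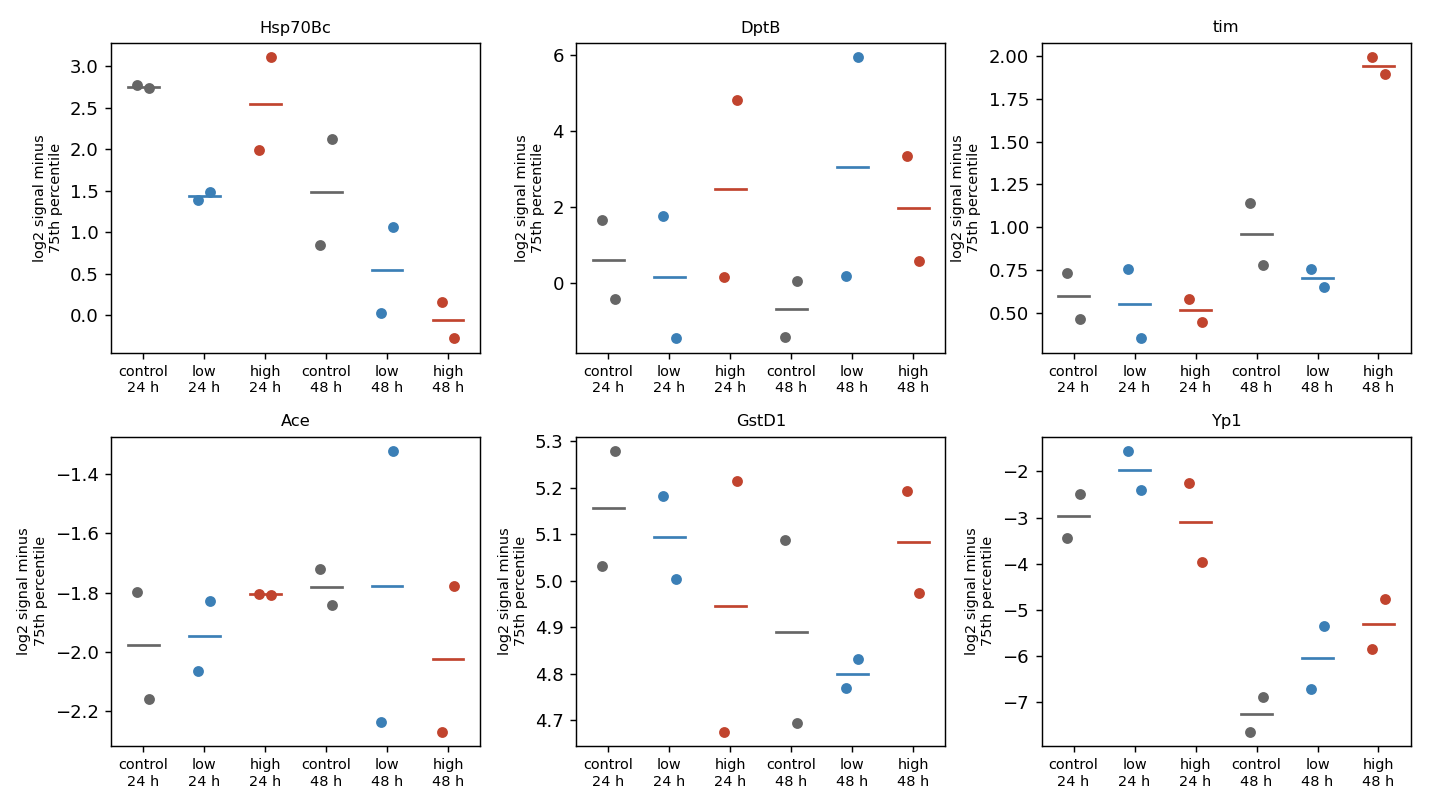
Signal of 6 genes on each array (points, log2 minus the 75th percentile of the array, with the group mean as a line) for the 6 groups on the horizontal axis. Relative to controls at 48 h, high-dose arrays had a log2 fold change of 0.98 for tim, -1.55 for Hsp70Bc, 2.65 for DptB, -0.24 for Ace and 0.19 for GstD1, none of which passed over all genes.

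Between the doses at 48 h, ribosomal proteins were higher in high-dose than in low-dose flies in 90 of 93 members, with a median of 0.35. The ribosomal genes sta, at 0.69 ± 0.17, RpS20, at 0.72 ± 0.18, and RpL26, at 0.62 ± 0.18, had among the smallest p. Photoreceptor genes were higher in 22 of 25 with a median of 0.40, including Arr1, at 0.81 ± 0.23, and the channel trpl, at 0.75 ± 0.27. UGTs were lower in 24 of 29 with a median of -0.49, and Ugt302K1, dim at the high dose, was at least 2.39-fold lower. Yolk and eggshell genes were higher in 17 of 17 with a median of 0.74, including the eggshell gene Cp15 at 1.61 ± 0.50.

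The ribosomal difference had an adjusted p of 2.21e-17 (0.86 with the estimate) and kept its call without any array, while under quantile scaling the median was 0.19, still called. Photoreceptor genes had an adjusted p of 0.00118 (0.989 with the estimate). The median was 0.65 without high 1, and the call ended without low 1 (0.21) or high 2 (0.21). UGTs had an adjusted p of 0.00182 (0.86 with the estimate), and the call ended without low 1 (-0.31) or high 2 (-0.09). The yolk and eggshell list had an adjusted p of 0.00277 (0.86 with the estimate). The median was 0.44 without high 2, 0.43 with normexp and 0.41, not called, without low 1. OXPHOS genes were at 0.19 with 72 of 91 higher (adjusted p = 0.00161, 0.989 with the estimate). The median was 0.28 without high 2, and the call ended without low 2 (0.21) or high 1 (0.12). Under quantile scaling the call also ended (0.07, adjusted p = 0.728). The subunits ND-AGGG and ND-42 went the other way, at -1.81 ± 0.55 and -1.28 ± 0.39. Male accessory gland genes were at 0.25 with 38 of 50 higher (adjusted p = 0.0354, 0.989 with the estimate). The median was 0.54 without low 1 and 0.59 without high 1, and the call ended without low 2 (0.06) or high 2 (-0.06). It also ended under quantile scaling (adjusted p = 0.234), with normexp (0.0902) and on the authors' values (0.07). The list holds Acp1, an adult cuticle protein gene caught by its symbol, lower at -3.58 ± 0.64. Acp1 was the only member of the 6 lists to pass adjusted over the list alone, and 0 passed over all genes. At an unadjusted p under 0.05 there were 37 ribosomal genes (36 higher and 1 lower), 5 photoreceptor genes, 3 UGTs, 2 yolk and eggshell genes, 9 OXPHOS genes and 3 accessory gland genes.

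Limma called 0 features between the doses at 48 h (smallest adjusted p = 0.0867), with 1999 at an unadjusted p under 0.05. The count was 33 without low 1, 68 without low 2, 6 without high 1, 3 without high 2, and 1 without either control array of 48 h or either low array of 24 h. Values that did not pass were the lipase-family gene dob at 1.32 ± 0.18, Drsl4 at 1.24 ± 0.18, tim at 1.24 ± 0.20 with its other probe at 0.50, Miox at 1.69 ± 0.31 and Gr58c, at least 2.73-fold higher. Lower values were VGAT, at least 1.38-fold lower, the dynein arm subunit ODA-Dnal1 at -1.14 ± 0.21, cact, the inhibitor of Toll signalling, at -1.30 ± 0.24 with its other probe at -0.47, and CG8799 at -2.07 ± 0.39.

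Over both times, low-dose flies had lower heat shock proteins and chaperones than controls, in 23 of 24 members with a median of -0.37. Hsp70Aa was at -0.90 ± 0.24, Hsp26 at -0.81 ± 0.23, Hsp70Bb at -1.09 ± 0.32 and Hsp68 at -0.75 ± 0.23. Fat body genes were higher in 13 of 15 with a median of 0.75, and to rose by 1.01 ± 0.24 when adjusted over the list alone. UGTs were higher in 20 of 29 with a median of 0.24, including Ugt302C1 at 0.37 ± 0.13, and Toll and Imd genes in 24 of 31 with a median of 0.16, including GNBP1 at 0.44 ± 0.15 and cact at 0.43 ± 0.17.

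The heat shock list had an adjusted p of 7.02e-11 (0.344 with the estimate), and its call held with any array left out. For fat body genes the adjusted p was 0.000494 (0.593 with the estimate), with medians of 0.49 without control 1 of 48 h and 0.37, not called, without low 2 of 48 h. For UGTs it was 0.00072 (0.593 with the estimate). The median was 0.16, not called, without low 1 of 48 h. For Toll and Imd genes it was 0.000494 (0.912 with the estimate). The median was 0.39 without low 1 of 48 h and 0.00, not called, without low 2 of 48 h. Male accessory gland genes were at -0.24 with 43 of 50 lower (adjusted p = 0.000842, 0.914 with the estimate), and the call ended without control 1 (-0.11) or low 2 (-0.10) of 48 h. Antimicrobial peptides were at 0.53 with 22 of 25 higher (adjusted p = 0.00692, 0.914 with the estimate). They were at 1.52 without low 1 of 48 h, and the call ended without control 2 (0.39) or low 1 (0.33) of 24 h or low 2 of 48 h (-0.17). Hemocyte genes were at 0.19 with 14 of 20 higher (adjusted p = 0.00862, 0.886 with the estimate). The median was 0.35 without low 1 of 48 h and 0.01, not called, without low 2 of 48 h.

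At the low dose over both times, P450 genes were at 0.13 with 52 of 80 higher (adjusted p = 0.0151, 0.886 with the estimate), including Cyp6a13 at 0.62 ± 0.15. They were at 0.07 without control 2 of 48 h, and the call ended without control 2 (0.03) or low 2 (0.08) of 24 h or low 1 (0.04) or low 2 (0.11) of 48 h. Proteasome genes were at -0.08 with 35 of 45 lower (adjusted p = 0.0292, 0.914 with the estimate). The median was -0.13 without control 1 of 24 h and -0.12 without low 1 of 48 h. The proteasome call ended without control 2 (-0.02), low 1 (-0.08) or low 2 (-0.07) of 24 h and without control 1 (-0.06), control 2 (-0.07) or low 2 (-0.01) of 48 h. Cuticle proteins were at 0.10 with 49 of 74 higher (adjusted p = 0.0459, 0.914 with the estimate). They were at 0.20 without control 2 of 24 h and 0.17 without low 1 of 48 h. The cuticle call ended without control 1 (-0.03) or low 1 (0.05) of 24 h, without control 1 (0.07) or low 2 (-0.04) of 48 h, and without either high array of 48 h (0.10).

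Without the dim filter the P450 and cuticle calls ended (adjusted p = 0.144 and 0.27). In the 10 lists called at the low dose over both times, limma found 0 members over all genes, and to alone passed adjusted over the list alone. At an unadjusted p under 0.05 there were 9 heat shock genes, 1 fat body gene, 4 UGTs, 3 Toll and Imd genes, 5 P450 genes, 2 cuticle genes, 1 antimicrobial peptide gene (lower), 1 hemocyte gene and 0 of the other 2 lists. Over all features limma called 0 (smallest adjusted p = 0.0917), with 615 at an unadjusted p under 0.05. The count was 2 without control 2, 3 without low 1 and 6 without low 2 of 24 h, and 3 without control 2, 2 without low 1 and 4 without low 2 of 48 h. Values that did not pass were Dci at 1.31 ± 0.23, asRNA:Eig63F-2 at 1.35 ± 0.29, Nt5a at 0.82 ± 0.19 and Pdf at 0.85 ± 0.20. Lower were the sugar-responsive sug at -0.76 ± 0.17 and Miox at -0.88 ± 0.22. CtsL2 (adjusted p = 0.415) is given no size, being dim in 3 of the 4 groups.

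Over both times, high-dose flies had higher antimicrobial peptides and Bomanins than controls, in 24 of 25 members with a median of 0.84. Drsl4 and Drsl3 rose by 0.56 ± 0.13 and 0.93 ± 0.22 when adjusted over the list alone, and Drsl5 was at 0.64 ± 0.22. Ribosomal proteins were slightly higher in 88 of 93 members with a median of 0.13, including RpS29 at 0.30 ± 0.13. Photoreceptor genes were higher in 20 of 25 with a median of 0.19, including ninaB, an enzyme of visual pigment synthesis, at 0.49 ± 0.18. Heat shock proteins were lower in 20 of 24 with a median of -0.11, including Hsp70Aa at -0.86 ± 0.24, Hsp83 at -0.45 ± 0.13 and the stress-induced RNA lncRNA:Hsromega at -0.74 ± 0.24. CO286976 alone passed limma over all features (adjusted p = 0.0034), with no size given, as it was well above background only in high-dose flies at 24 h.

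The adjusted p was 2.39e-10 for antimicrobial peptides, whose call held without any array, 2.86e-11 for ribosomal proteins, 0.000131 for photoreceptor genes and 0.00029 for heat shock proteins, each at 0.905 with an estimated correlation. The ribosomal median was 0.07 without control 1 of 24 h, 0.08 without high 1 of 48 h and 0.07 under quantile scaling. Photoreceptor genes were at 0.31 without high 1 and at 0.05, not called, without high 2 of 48 h. Heat shock proteins were at -0.29 without high 2 of 24 h, -0.21 without control 1 and -0.16 without high 2 of 48 h, and at -0.14 and not called without high 1 of 24 h. Hemocyte genes were at 0.22 with 15 of 20 higher (adjusted p = 0.00964, 0.905 with the estimate), including the prophenoloxidase PPO1 at 1.04 ± 0.42, and were not called without high 2 of 24 h (0.07) or high 1 of 48 h (0.11). Fat body genes were at 0.19 with 12 of 15 higher (adjusted p = 0.0195, 0.905 with the estimate), including the storage protein Lsp2 at 1.92 ± 0.51. Their median was 0.30 without control 2 and 0.29 without high 1 of 24 h and 0.34 without control 2 of 48 h, and the call ended without high 2 of 24 h (-0.01), control 1 of 48 h (0.08) and high 1 of 48 h (0.16). It also ended with normexp (adjusted p = 0.122) and without the dim filter (0.0611).

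Male accessory gland genes of high-dose flies over both times were at -0.11 with 38 of 50 lower (adjusted p = 0.0195, 0.954 with the estimate), including Sfp79B at -0.94 ± 0.37. Their median was -0.22 without high 1 of 24 h, -0.21 without control 2 of 48 h and -0.27 without high 2 of 48 h. The accessory gland call ended without control 2 (-0.07) or high 2 (0.02) of 24 h and without control 1 (0.00) or high 1 (0.04) of 48 h. Odorant-binding proteins were at 0.08 with 29 of 45 higher (adjusted p = 0.0421, 0.905 with the estimate), while Obp56b passed as lower when adjusted over the list alone, without a size because it was not well above background in high-dose flies at either time. Their median was 0.23 without control 2 and 0.24 without high 2 of 24 h and 0.16 without control 1 of 48 h. The odorant-binding call ended without control 1 (-0.04) or high 1 (0.07) of 24 h and without control 2 (0.10), high 1 (0.19) or high 2 (0.11) of 48 h. It also ended under quantile scaling (adjusted p = 0.0538), on the authors' values (0.0594) and without the dim filter (0.0843), and with normexp the median was 0.14.

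In the 8 lists called at the high dose over both times, limma found 0 members over all genes, and adjusted over the list alone 2 antimicrobial peptide genes and 1 odorant-binding protein gene passed. At an unadjusted p under 0.05 there were 5 antimicrobial peptide, 0 ribosomal, 1 photoreceptor, 6 heat shock, 1 hemocyte, 2 accessory gland, 2 fat body and 3 odorant-binding protein genes. Over all features 679 reached that unadjusted p. The count of 1 became 4 without control 2 of 24 h, 11 without control 2 of 48 h and 2 without any 1 of the 4 high-dose arrays or either low array of 48 h. Values that did not pass were Pdf at 1.06 ± 0.20 and nkt at 0.58 ± 0.15, and, on the lower side, CG8799 at -1.73 ± 0.27, ODA-Dnal1 at -0.79 ± 0.15 and sug at -0.89 ± 0.17.

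The effect of the low dose differed between the times for digestive enzymes, whose difference was below 0 in 46 of 52 members with a median of -0.80, from higher than controls at 24 h to lower at 48 h. The trypsins betaTry, lambdaTry and deltaTry had differences of -1.45 ± 0.49, -1.15 ± 0.42 and -0.69 ± 0.26, and Npc2e had -2.72 ± 0.93. That list had an adjusted p of 2.07e-10 (0.912 with the estimate), and its call held with any array left out. Smaller negative differences were called for male accessory gland genes, at -0.29 with 44 of 50 lower (adjusted p = 0.000858), ribosomal proteins, at -0.14 with 75 of 93 lower (adjusted p = 0.000858), and hemocyte genes, at -0.26 with 14 of 20 lower (adjusted p = 0.0198), each 0.912 with the estimate. Among hemocyte genes the collagen genes vkg and Col4a1 had differences of -1.01 ± 0.30 and -0.58 ± 0.27. The accessory gland difference was -0.45 without control 2 and -0.50 without low 1 of 48 h, and was not called without low 1 of 24 h (-0.26) or control 1 (-0.11) or low 2 (-0.11) of 48 h. The ribosomal difference was -0.25 without control 2 of 24 h or low 2 of 48 h, and was not called without control 1 of 24 h (-0.06), control 1 of 48 h (-0.11) or low 1 of 48 h (-0.05). The hemocyte difference was -0.54 without low 2 of 48 h, and was not called without low 1 of 24 h (-0.55), control 2 of 48 h (-0.23) or low 1 of 48 h (-0.09). With normexp the ribosomal and hemocyte calls ended (adjusted p = 0.108 and 0.16), and under quantile scaling the ribosomal call ended at -0.04 (adjusted p = 0.196).

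In those 4 lists limma called 0 members over all genes or adjusted over the list alone, with 8 digestive enzymes, 1 ribosomal, 2 hemocyte and 0 accessory gland genes at an unadjusted p under 0.05. Over all features limma called 0 time differences of the low dose effect (smallest adjusted p = 0.125), with 666 at an unadjusted p under 0.05. The count was 9 without low 2 of 24 h, and 4 without control 2, 16 without low 1 and 1 without low 2 of 48 h. Differences that did not pass included Lrrk at 1.28 ± 0.27, the cuticle gene Cpr65Ec at 1.35 ± 0.38, Cypl at 0.71 ± 0.22 and the histone gene His1:CG33804 at 1.16 ± 0.37. CtsL2 did not pass either (adjusted p = 0.433) and is given no size, since it was well above background in 1 of the 4 groups. Negative were Hacl at -1.13 ± 0.24, Peritrophin-15a, of the gut lining, at -1.88 ± 0.43, the ion transporter Ncc69 at -1.33 ± 0.31 and OtopLc at -1.55 ± 0.36.

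The effect of the high dose differed between the times for CG15773 (adjusted p = 0.0256) and for CO286976 (adjusted p = 0.0103), the only 2 past limma, each with the lower effect at 48 h. No size is given, since each was well above background in 1 of the 4 groups, CG15773 in 48 h controls and CO286976 in high-dose flies at 24 h. Yolk and eggshell genes had a positive difference in 16 of 17 members with a median of 1.00 (adjusted p = 0.0252 for the list), including the eggshell gene Cp18 at 1.16 ± 0.37. Ribosomal proteins had one in 77 of 93 with a median of 0.22 (adjusted p = 0.00117), although RpL34b fell by 1.38 ± 0.25 when adjusted over the list alone. Photoreceptor genes had a positive difference in 20 of 25 with a median of 0.44 (adjusted p = 0.0281 for the list), including Arr1 at 0.99 ± 0.32 and the opsin ninaE at 0.65 ± 0.31. Each of the 3 lists had an adjusted p = 0.847 with an estimated correlation. The yolk and eggshell difference was 1.61 without high 1 of 24 h, and was not called without high 2 of 24 h (0.25), either low array of 48 h (1.00) or high 1 of 48 h (0.77). The ribosomal difference was 0.33 without high 2 of 48 h, and was not called without control 2 of 24 h (0.11) or high 1 of 48 h (0.10). The photoreceptor difference was 0.71 without high 1 of 48 h, and was not called without control 1 (0.23) or high 2 (0.31) of 24 h, either low array of 48 h (0.44) or high 2 of 48 h (0.17). Under quantile scaling the ribosomal (0.12) and photoreceptor calls ended (adjusted p = 0.119 for each). With normexp the yolk and eggshell (0.47) and photoreceptor calls ended (adjusted p = 0.0584 for each), and without the dim filter the photoreceptor call did (0.0597).

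For the 3 lists of the high dose time difference, limma called 0 members over all genes and RpL34b alone when adjusted over the list alone, with 11 ribosomal, 4 yolk and eggshell and 1 photoreceptor gene at an unadjusted p under 0.05. Over all features 2039 reached that unadjusted p. The count of 2 was 0 without control 1, 1 without control 2, 1 without either low array and 4 without high 1 of 24 h, and 8 without control 2, 6 without either low array and 13 without high 1 of 48 h. Not passing were sr at 2.73 ± 0.52, FarO at 1.44 ± 0.28, Cpr65Ec at 1.92 ± 0.38 and SNRPG at 1.74 ± 0.38. Negative ones were obst-B at -3.49 ± 0.56, Mrp5 at -2.22 ± 0.37, sphe at -3.48 ± 0.60 and the nuclear export gene emb at -1.23 ± 0.22.

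Control flies at 48 h differed from those at 24 h in yolk and eggshell genes, which were lower at 48 h in 15 of 17 members with a median of -1.62. Yp1 was at least 13-fold lower (adjusted p = 0.0414), and the eggshell genes Cp16, Cp19 and Vm26Ab were at least 44.7-fold, 50.5-fold and 5.50-fold lower, in samples labelled as male. Fat body genes were lower in 12 of 15 with a median of -1.90, including the storage proteins Lsp2, at -3.53 ± 0.73, and Fbp2, at -5.38 ± 1.54, and the yolk protein Yp2, at -2.62 ± 0.75. Heat shock proteins were lower in 19 of 24 with a median of -0.49, including Hsp26 at -1.45 ± 0.32. Muscle genes were lower in 23 of 23 with a median of -0.43, including the myosin light chain Mlc1 at -0.58 ± 0.23, and OXPHOS genes in 79 of 91 with a median of -0.33, including ND-B18 at -0.74 ± 0.19. Time and slide cannot be told apart here.

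The adjusted p was 9.47e-09 for yolk and eggshell (0.519 with the estimate), 5.50e-05 for fat body (0.56 with the estimate) and 0.000289 for heat shock proteins (0.697 with the estimate), and these calls held without any array. It was 1.31e-06 for muscle and 1.02e-09 for OXPHOS, each 0.697 with the estimate. The muscle median was -0.66 without control 1 of 24 h and -0.28 and -0.69 without control 1 and control 2 of 48 h, and the OXPHOS median was -0.52 and -0.14 without control 1 and control 2 of 24 h. Proteasome genes were at -0.24 with 39 of 45 lower (adjusted p = 5.25e-06, 0.697 with the estimate), and at -0.14 without control 2 of 24 h. Male accessory gland genes were at -0.53 with 45 of 50 lower (adjusted p = 1.51e-05, 0.705 with the estimate), and at -0.29 without control 2 of 48 h. In contrast, the seminal fluid gene Sfp60F rose by 3.37 ± 0.33, and Sfp33A1, not well above background at 24 h, passed as higher adjusted over the list alone. Ribosomal proteins were at -0.16 with 77 of 93 lower (adjusted p = 3.47e-05, 0.705 with the estimate). The median was -0.27 without control 1 of 24 h and -0.10 without control 2 of 48 h, and the call ended without control 2 of 24 h (-0.06). Under quantile scaling that median turned to 0.06 and was not called (adjusted p = 0.368), and OXPHOS, muscle and proteasome genes were at -0.11, -0.23 and -0.16, still called. With normexp the yolk and eggshell median was -0.89, still called. Cuticle proteins were at -0.22 with 51 of 74 lower (adjusted p = 0.035, 0.705 with the estimate). The median was -0.35 without control 1 of 24 h and -0.40 without control 2 of 48 h, and the call ended without control 2 of 24 h (-0.07) or control 1 of 48 h (-0.15). The cuticle gene Lcp3 was at least 4.14-fold higher and passed adjusted over the list alone, and the cuticle call also ended without the dim filter (adjusted p = 0.0691).

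Testis genes of controls were at -0.23 with 21 of 29 lower (adjusted p = 0.0382, 0.705 with the estimate), although mia was at 0.62 ± 0.17, and were not called without control 1 (-0.25) or control 2 (-0.19) of 24 h or control 2 of 48 h (-0.15). Antioxidant and metallothionein genes were at -0.23 with 21 of 28 lower (adjusted p = 0.0452, 0.697 with the estimate), including the metallothionein MtnB at -1.76 ± 0.67. They were not called without control 1 (-0.22) or control 2 (-0.14) of 24 h, control 2 of 48 h (-0.19) or either high array of 48 h (-0.23). The testis and antioxidant calls also ended under quantile scaling (adjusted p = 0.854 and 0.494), with normexp (0.224 for each) and without the dim filter (0.172 and 0.173). Over all genes, limma called 1 member each of the yolk and eggshell, fat body (both Yp1) and accessory gland (Sfp60F) lists. Adjusted over the list alone, 9 yolk and eggshell genes and 7 fat body genes fell and 1 fat body gene rose, 2 accessory gland genes rose, 1 heat shock gene fell and 1 cuticle gene rose. The other 6 lists had 0 by either count, and at an unadjusted p under 0.05 there were 23 OXPHOS, 7 muscle, 10 proteasome, 8 ribosomal, 2 testis and 3 antioxidant genes.

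Over all features, 119 passed limma between the control groups, 114 higher and 5 lower at 48 h, with 2348 at an unadjusted p under 0.05. Of the 114, 87 had no NCBI match and 62 were not well above background on either control array of 24 h, while the 48 h control arrays had the highest shares of probes above background. Named genes higher at 48 h were the mitochondrial complex I subunit ND6 at 4.39 ± 0.46, the peroxisomal oxidase Acox3, at least 3.17-fold, CCHa1-R, at least 2.41-fold, Glyat, at least 2.37-fold, CG9664, at least 3.12-fold, CG15773, at least 1.31-fold, and CG7606, at least 1.32-fold. The odorant-binding protein gene Obp56e fell by 1.77 ± 0.30. The count was 18 and 61 without control 1 and control 2 of 24 h, and 8 and 66 without control 1 and control 2 of 48 h.

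The effects of the 2 doses share their control arrays. Across 18008 features, which are not independent replicates, the log2 fold changes of the doses correlated at 0.64 at 24 h, where unchanged groups simulated against shared controls gave 0.50, and at 0.43 at 48 h, where they gave 0.50. Covariance was 0.136 at 24 h and 0.103 at 48 h, beside 0.0766 in each simulation. The sign was the same for 77.1% of features at 24 h and 58.7% at 48 h, beside 66.7% by simulation. At 24 h 0 features were called by limma at both doses, with 950 and 726 at an unadjusted p under 0.05 at the low and high dose. At 48 h 1 was called at both, CG7606, dim in all groups but the shared controls. The controls were not split between the doses, so part of any excess may come from the shared controls.

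Genes of organophosphate action, detoxification, stress and immunity chosen in advance did not pass in any comparison. Ace, which encodes acetylcholinesterase, was at 0.03, 0.17, 0.00 and -0.24 (SE 0.30) for the low and high dose at 24 h and the low and high dose at 48 h. In the same order, the P450 genes were at 0.18, 0.05, -0.31 and 0.12 (SE 0.24) for Cyp6g1, at -0.11, -0.04, -1.20 and -1.15 (SE 1.02) for Cyp6a2 and at -0.07, -0.21, 0.66 and -0.32 (SE 0.49) for Cyp12d1-p. The glutathione transferase GstD1 was at -0.06, -0.21, -0.09 and 0.19 (SE 0.23), and GstD2 at -0.83, -0.29, -1.59 and -2.29 (SE 1.43). Hsp70Bc was at -1.32, -0.21, -0.94 and -1.55 (SE 0.51), and the diptericin gene DptB at -0.46, 1.86, 3.73 and 2.65 (SE 2.17). The smallest adjusted p among these 8 genes over the 11 comparisons was 0.344, for Hsp70Bc.

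Another 11 lists were not called in any of the 11 comparisons. The cholinergic synapse list, which holds Ace and the acetylcholine receptors, had medians from -0.19 to 0.23 over the comparisons (smallest adjusted p = 0.173), and 0 of its 15 genes reached an unadjusted p under 0.05 in any. Glutathione S-transferases lay between -0.11 and 0.20 (0.224), carboxylesterases between -0.31 and 0.15 (0.119), and the Turandot and Jak/Stat list between -0.15 and 0.45 (0.707), with the smallest adjusted p in parentheses. In the same form, apoptosis and JNK genes lay between -0.08 and 0.18 (0.121), insulin, Akh and starvation genes between -0.04 and 0.25 (0.21), lipid synthesis and desaturation genes between -0.42 and 0.24 (0.128), neuron genes between -0.19 and 0.22 (0.224), and ecdysone and juvenile hormone genes between -0.19 and 0.07 (0.403). Activity-regulated genes, which respond to neuronal firing, lay between -0.20 and 0.31 (0.0871) and clock genes between -0.12 and 0.51 (0.0604). Limma passed 0 of the members of the 11 lists over all genes. Adjusted over the list alone and summed over the comparisons, there were 8 passes of clock genes (4 up and 1 down between the doses at 48 h), 3 of activity-regulated, 2 each of lipid, insulin and neuron, 1 each of ecdysone and glutathione S-transferase genes and 0 in the other 4 lists. Among uncalled lists the median, mean and test at times differed in sign, as for antimicrobial peptides in controls (median -0.36, mean -0.19, upward test).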

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

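The single-array and immune-state tests of the antimicrobial peptides and the fat body test of the yolk and eggshell genes were chosen only after the result was seen, and the predictions for the other tests were written before their values. Groups of 2 arrays are too small for a test of outlying samples.

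The tests of a difference between the times singled out 9 results. The low dose effect differed between 48 h and 24 h for digestive enzymes (-0.80), male accessory gland genes (-0.29), ribosomal proteins (-0.14) and hemocyte genes (-0.26). The high dose effect differed for CG15773 (-4.29), CO286976 (-4.07), ribosomal proteins (0.22), yolk and eggshell genes (1.00) and photoreceptor genes (0.44). The values of CG15773 and CO286976 rest on signal not well above background in 3 of 4 groups and are no measure of size. Each was found by the test of the difference itself, with camera at the preset correlation or limma. With the correlation estimated, 0 of the 7 list differences passed (adjusted p = 0.912 for the low dose and 0.847 for the high dose).

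For antimicrobial peptides at the high dose over both times, the highest adjusted p with each of 8 arrays left out was 1.73e-05, and the smallest median over 4 other scalings was 0.69, which argues against a single array and against scaling as the source. The immune state of single samples, whatever their dose, stays open, since an exact permutation test of the trend, with doses permuted within each slide, gave p = 0.136 among 8100 arrangements. The low-dose arrays of 48 h alone spanned -1.10 to 2.02 in this list. A response to the dose and infection of some cultures could both give these values.

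For heat shock proteins at the low dose over both times, the median lay at percentile 0 of 10000 random lists matched on mean signal. This argues only against a position effect set by brightness. Over those 4 alternatives the median closest to 0 was -0.37, so it did not depend on them. The stress state of single samples was not decided: 36 arrangements of low-dose and control arrays within each slide allow no p under 0.0556, which was reached, so the exact test could not speak against it. The direction is opposite to that of a heat shock response, and a lower temperature or less handling of the low-dose samples could give it as well as the compound.

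Without the yolk protein genes, the yolk and eggshell list in controls had a median of -1.41, which argues against fat body transcripts alone. The alternative closest to 0 gave -0.89, still lower. Whether female flies or tissue were in the 24 h samples stays open: 13 measured oocyte transcripts had a median of -0.094 (SE 0.26), with 9 of them lower at 48 h. Bright exu and orb could mask a small female share. That median met the advance bound against this explanation, but by less than its spread, a weighing chosen afterwards. The lowest were gnu (-1.70, well above background on 1 of the 48 h control arrays), yl (-1.66) and alphaTub67C (-1.64), and the 4 above 0 were fs(1)N (0.32), swa (0.29), grk (0.22) and exu (0.12). Male accessory gland (-0.53) and testis genes (-0.23) were also lower at 48 h (adjusted p = 0.705 each with an estimated correlation), where loss of a female share alone would raise them.

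Splits of the 8 arrays, save the one that follows the slide, were compared with slide as a block. For lists the real count, 9 at each dose, was typical of chance. At least as many came from 20 of 34 splits (real included) at the low and 18 at the high dose (highest other 15). For genes the real count was 0, which every split reaches (highest other 1 at the low, 2 at the high dose), so that decides nothing.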

How the results depend on the processing

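Signal over background limits the gene values: the features called within a time were each well above background in only 1 group, so their fold is a bound. Among the tests of this part, the fit to NCBI genes only, list medians with dim values raised to the lowest signal well above background and 4 of the 6 digit pairs were chosen only after the result was seen. Where a count or call below changed, the cause was not tested, except that fewer features or residual degrees of freedom enter by construction where stated. Counts kept to within 1.5 times under centring on the median and the authors' values in all comparisons, and under the 1.5-fold threshold. Of list results with the estimate, fry, quantile scaling or no dim filter, 121 stayed, 170 no longer passed and 1 reversed. Of the values of named genes, 1759 kept their sign and their side of the threshold, whatever the change in size. Another 57 no longer passed, 38 that did not pass changed sign and 2 passed only there. With the estimated correlation and with fry, 0 of 40 list calls were left. List calls numbered 44 with quantile scaling, 35 without the filter on dim probes and 39 to 50 with an array left out.

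With normexp background correction the counts of features called went from 0 to 1 for the low dose at 24 h, from 1 to 0 for the high dose at 24 h, from 1 to 0 for each dose at 48 h, from 2 to 1 between the doses at 24 h, from 0 to 1 for the low dose and 1 to 0 for the high dose over both times, from 2 to 0 for the time difference of the high dose and from 119 to 23 in controls. Quantile scaling gave 4 and 3 for the low and high dose at 24 h, 3 for the high dose at 48 h, 5 and 2 between the doses at 24 h and 48 h, 1 and 4 for the low and high dose over both times, 1 and 4 for their time differences, and 2 features called at both doses at 24 h in place of 0. Without the filter on dim probes there were 2 for the low dose at 48 h, 4 between the doses at 24 h and 1 for the time difference of the high dose. With only probes well above background on all arrays there were 0 for the high dose at 24 h, for each dose at 48 h, between the doses at 24 h, for the high dose over both times and for its time difference, 1 for the low dose over both times and 31 in controls. A filter on all arrays removes genes dim in 1 group by construction.

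With NCBI genes only, added after the data were seen, there were 1 for the low dose and 0 for the high dose at 24 h, 3 for the high dose at 48 h, 1 between the doses at each time, 0 for the high dose over both times and 22 in controls. A trended robust prior gave 0 for the high dose at 24 h, each dose at 48 h, the high dose over both times and its time difference, 1 for the low dose over both times and 34 in controls. A fit to the arrays of 1 time gave 3 for the high dose at 24 h, 0 for the high dose at 48 h and 1 between the doses at each time, and for the low dose at 48 h it called 1 feature other than CG7606. With slide as an additive block the count for the high dose over both times was 0. At an adjusted p under 0.10 there were 1, 4 and 3 for the low dose at 24 h and the low and high dose at 48 h, 6 and 1 between the doses, 1 for the low dose over both times, 5 for the time difference of the high dose and 225 in controls.

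With the final digit of the sample titles as a replicate block, 0 features were called in each of the 11 comparisons, in a fit with 2 residual degrees of freedom. Differences between an array with a shared digit and its group mate correlated across features at -0.16 to 0.05 over the 6 pairs of groups within a time. In antimicrobial peptides (and Toll and Imd genes) the 48 h arrays with the digit common to 3 groups exceeded their mates (antimicrobial mean by 0.32, 3.54 and 1.08 for control, low and high), while signs differed at 24 h, so whether samples with 1 digit belong together stays open.

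With each array left out in turn, counts ran from 0 to 14 and from 1 to 6 for the low and high dose at 24 h, and from 0 to 39 and from 0 to 27 at 48 h. Between the doses they ran from 2 to 15 at 24 h and from 0 to 68 at 48 h. Over both times they ran from 0 to 6 for the low and from 1 to 11 for the high dose, for the time differences from 0 to 16 and from 0 to 13, and in controls from 8 to 132. With an array left out, 752 list results kept their call, 112 lost it and 12 reversed. Arrays outside a comparison leave its median unchanged and swell the 752. Those with a reversal ranged, in log2 fold change, from -0.0198 to 0.37 for cuticle proteins (low dose, 24 h), from -0.55 to 2.35 for antimicrobial peptides, -0.46 to -0.0528 for digestive enzymes and -0.15 to 0.65 for Toll and Imd genes (low dose, 48 h). Between the doses at 24 h they ranged from -0.34 to 1.12 for antimicrobial peptides, -0.38 to 0.11 for accessory gland genes and -1.34 to 0.0535 for yolk and eggshell genes, and at 48 h from -0.0623 to 0.59 for accessory gland genes. Over both times they ranged from -0.17 to 1.52 for antimicrobial peptides and -0.13 to -0.00699 for the proteasome at the low dose, and from -0.27 to 0.0373 for accessory gland genes at the high dose. Under quantile scaling the ribosomal list of the control comparison reversed to 0.0578.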

Other observations

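Families of genes that share a symbol stem were tested with camera in all comparisons, a choice made after the data were seen, among 85 families of at least 8 members. Maltases of the Mal-A cluster, which digest sugars, were higher at the low dose and 24 h in 8 of 8 members with a median log2 fold change of 0.95 (adjusted p = 0.00131, and adjusted p = 0.963 with an estimated correlation). They were lower in 8 of 8 members at the high than at the low dose at 24 h, with a median of -0.55 (adjusted p = 0.000633, and adjusted p = 0.985 with an estimated correlation). The seminal fluid family Sfp was lower at the low dose and 48 h in 24 of 27 members, with a median of -0.31 (adjusted p = 0.000286, and adjusted p = 0.995 with an estimated correlation). The accessory gland list, which holds these genes, lost its call there without low 2 (-0.14).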
